A study of Rattus norvegicus with 78 samples.

How the data were processed

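The data were 78 arrays of RNA from rat sperm, 1 per sample: 20 from corn oil rats, 20 from rats given DBCP at 5 mg/kg/day, and 19 from each of these treatments after a recovery period whose length is not given in the sources used here. Per the labels' protocols, sperm were let out of punctured cauda epididymides, pelleted, treated briefly with an ammonium chloride buffer, which lyses red cells, and washed, and RNA was taken with a kit that separates large from small RNA; biotin was the label. The labels name the tissue as sperm, while the title of the series names testis. The exposure of 3 months is stated in the text of the series.

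The values are log2 summaries per probe set as deposited by the authors, with 29214 probe sets per array and 0 missing values. Limma is the only tool that the submitters' processing notes name, without a version. The background correction, the normalization and the summarisation are not given in the sources used here. From the values themselves, the arrays had medians between 6.55 and 6.75. They were taken to be on a common scale, and no further scaling was applied in the main fit. The spread of these medians is as large as many of the list differences below, so small differences can depend on the scaling. The platform annotation gave 1 gene symbol to 15310 probe sets (14506 genes, 527 of them with more than 1 probe set), several to 323 and none to 13581, which are unnamed here; 15279 matched the reference gene table by Entrez identifier. No gene is named from a probe set with several symbols. No control probe set names were found (0), so the planned comparison of 3' with 5' control signals as a proxy of RNA integrity was not run.

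A group means model was fitted to all 78 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups shared an estimate of the spread for each probe set. There were 5 contrasts: DBCP against corn oil at the end of exposure, DBCP against corn oil after recovery, the interaction of both, and recovery against end of exposure within corn oil and within DBCP rats. P-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. Adjusted p-values of genes are from this fit unless another tool is named.

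The comparisons, the test, the 23 gene lists, the rule for named genes and the other settings listed first below were fixed before the data were examined. The lists cover spermatid chromatin condensation, sperm tail, acrosome and egg binding, sperm-type energy metabolism, sperm ion channels and motility signalling, meiosis, spermatid regulators of transcription, translation and kinase signalling, epididymal principal cells, epididymal basal and clear cells, stroma with smooth muscle and endothelium, leukocytes, erythrocytes, Sertoli cells, Leydig cells, the p53 and DNA damage response, DNA repair, glutathione with xenobiotic metabolism and oxidative stress, heat shock and unfolded protein response, immediate early genes, apoptosis, cytosolic ribosomal proteins, the respiratory chain and the cell cycle. The list of spermatid regulators also holds other spermatid genes, such as Spata18, Spata20 and Spem1. Of 648 members 562 were on the array. Each gene entered by its probe set of highest mean. The lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted within a contrast. The mean level of each list per array was compared between groups with a two-sided permutation test (100000 resamples), adjusted over 115 tests.

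The rule for named genes took the 10 largest rises and the 10 largest falls among passing probe sets with 1 symbol. Where fewer than 10 passed, it took the 5 genes of smallest p. It took up to 3 passing members of each list, or the 2 brightest where none passed, and 13 genes named in advance in both DBCP contrasts. The count of arrays beside a value is the number in the group named earlier that lay beyond the mean of the group it was compared with.

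The alternatives were quantile normalization, centring on the array median, filters on dim probe sets, array weights, a trended robust variance prior, fits on the groups of a contrast alone, the replicate number as a block, the 2 sets of replicate numbers (1 to 10, 11 to 20) as a block, the epididymal principal cell and leukocyte levels as covariates, a plain 2-sample t statistic, an adjusted p of 0.10, 1 probe set per gene and leaving out each array. Added after the data were seen were annotated probe sets alone, fits without the 6 arrays whose limma array weight was under 0.5, leukocyte and erythrocyte levels as covariates, each set of replicate numbers alone, and combinations of these. Lists of natural killer and cytotoxic T cells, macrophages and dendritic cells, neutrophils, B cells, interferon-induced genes and the proteasome were also added then.

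The fit was tested on simulated data for the comparison of DBCP with corn oil at the end of exposure, with 29214 probe sets, 200 of them changed, in 20 runs. It recovered 59.4% of changes of 0.25, 94.9% of changes of 0.5 and 99.8% of changes of 1 (log2), with a median of 3 false calls and at most 21. The changed probe sets were drawn at random, with all sizes mixed in each run, so these shares are averages over all probe sets. They were not measured for genes of larger standard error, such as Akap4 (0.19, against a median of 0.06). With no change simulated for 14506 genes, camera with the preset correlation called a median of 4 of 23 lists and at most 9, and camera with an estimated correlation a median of 0 and at most 1. Permutation tests and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.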

Results

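The series measured transcripts of sperm from the cauda epididymis of rats on a whole-transcript rat array, with 1 array per sample and 78 arrays in 4 groups. Rats received corn oil (20 arrays) or 5 mg/kg/day of 1,2-dibromo-3-chloropropane (DBCP, a soil fumigant against nematodes that is toxic to male germ cells; 20 arrays) for 3 months. The other rats had a recovery period after the exposure: 19 arrays came from corn oil rats and 19 from DBCP rats. The values are on the log2 scale, and the medians of the arrays lay between 6.55 and 6.75. Any 2 arrays correlated at r between 0.860 and 0.988 across probe sets, which are not independent replicates. Differences are log2 values with their standard error (SE). Positive values are higher in DBCP rats, or, in the comparisons over time, higher after recovery. The number of arrays limits the precision: the median SE of the comparison at the end of exposure was 0.06.

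The comparison of 20 DBCP with 20 corn oil arrays at the end of exposure asked whether the toxicant left a mark in sperm transcripts. Transcripts that spermatids make late in their development stood somewhat higher on the DBCP arrays. Transcripts of leukocytes, stroma and red cells stood somewhat lower, but 0 probe sets passed limma's test. The list called spermatid regulators had a median log2 difference of 0.25, with 22 of 23 members above 0. It holds kinases and RNA-binding and transcription factors, but also other spermatid genes such as Spata18, Spata20 and Spem1, so it does not show regulators alone. The leukocyte list had a median of -0.14, with 28 of 29 members below 0. Of the 5 genes of smallest p, the first was Asns, the asparagine synthetase (0.45 ± 0.09, limma adjusted p = 0.103, above the corn oil mean on 18 of 20 DBCP arrays). The next were Stard10, a lipid transfer protein (0.54 ± 0.12), Eno1, a glycolytic enolase (0.33 ± 0.07), Uchl1, a ubiquitin hydrolase of germ cells and neurons (0.34 ± 0.08), and Fndc8 (0.55 ± 0.12). Each of these 4 had a limma adjusted p of 0.120.

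Genes named in advance did not pass either. Akap4, the main protein of the fibrous sheath of the sperm tail, had a log2 difference of 0.63 ± 0.19 (limma adjusted p = 0.161). It lay above the corn oil mean on 16 of 20 DBCP arrays. The protamines, which pack sperm DNA, had differences of 0.17 ± 0.07 (Prm1) and 0.51 ± 0.17 (Prm2). The transition proteins that they replace had 0.53 ± 0.22 (Tnp1) and 0.15 ± 0.13 (Tnp2). Ldhc, the lactate dehydrogenase of germ cells, stood at 0.40 ± 0.15, while Odf1 of the outer dense fibres and Smcp of the mitochondrial capsule stood at 0.03 ± 0.03 each. Both had corn oil means near the top of the scale (14.10 and 14.15, highest value on any array 14.69), so they could hardly show a rise. Clu, the secreted chaperone clusterin, had 0.28 ± 0.08 and Gstm1, a glutathione transferase, 0.27 ± 0.11. Cdkn1a, a p53 target that halts the cell cycle, had 0.03 ± 0.05. Mgmt, which repairs alkylated guanine, had 0.08 ± 0.05, and Hmox1, the inducible heme oxygenase, -0.04 ± 0.07.

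By gene list, camera with its preset correlation placed 10 of the 23 lists above the other genes and 3 below. Adjusted over the list alone, 11 of 23 spermatid regulators passed, all above 0. The brightest were Spata18 (0.43 ± 0.11) and Spata3 (0.40 ± 0.13). In the same way 8 of 17 chromatin condensation genes and 7 of 25 tail genes passed. In the acrosome list 4 of 25 did (Crisp2, a sperm protein of egg binding, 0.39 ± 0.15). The energy metabolism list had 4 of 17 (Gapdhs, the glycolytic enzyme of the tail, 0.49 ± 0.15) and the ion channel list 2 of 14 (Ppp1cc, a phosphatase of motility, 0.33 ± 0.11). Over all probe sets, 0 members of these lists passed. The respiratory chain (median 0.15, 41 of 47 above 0), ribosomal protein (0.09, 53 of 64), glutathione (0.09, 27 of 38) and heat shock lists (0.05, 15 of 20) were the other 4 lists placed higher. The leukocyte list was placed lower (camera adjusted p = 2.64e-06), with Cd74, the chaperone of class II antigen presentation, at -0.21 ± 0.10 and Lyz2, lysozyme, at -0.36 ± 0.15. So were the stroma list (0.00486; the matrix proteoglycan gene Dcn -0.10 ± 0.14) and the erythrocyte list (0.00909; the globin genes Hbb -0.28 ± 0.14 and Hbb-b1 -0.34 ± 0.14). All 13 calls were lost with an estimated correlation, where the adjusted p lay between 0.216 and 0.270. The fry test gave 2, chromatin condensation and ion channels (adjusted p = 0.0407 each).

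The lists of p53 and DNA damage response, DNA repair, apoptosis, immediate early genes, cell cycle, meiosis, and Sertoli, Leydig and epididymal principal cells had medians between -0.05 and 0.01, and camera called none of them. Several lay near or below the array median, with mean levels in corn oil rats of 6.18 (meiosis), 6.52 (cell cycle) and 6.66 (DNA repair). Mgmt and Hmox1 lay there too, so values near 0 do not show that no response occurred. Of the mean list levels per array, 2 of 23 passed the two-sided permutation test after Benjamini-Hochberg adjustment over the 115 tests. They were the ion channel list (0.12 ± 0.05, permutation test adjusted p = 0.0462) and the epididymal basal and clear cell list (0.10 ± 0.03, adjusted p = 0.0462), each above the corn oil mean on 17 of 20 DBCP arrays. With quantile normalization neither call held (permutation test adjusted p = 0.0586 for each, differences of 0.11 and 0.09), and 2 lower lists passed in their place, leukocytes (-0.16, adjusted p = 0.042) and stroma (-0.09, adjusted p = 0.0484). The basal and clear cell list had a median of only 0.02 beside this mean, with Foxi1, a transcription factor of clear cells, at 0.51 ± 0.14. The medians and means of the epididymal principal cell and DNA repair lists had opposite signs, as had the median and the camera direction of the DNA repair and Sertoli lists.

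With limma 3386 probe sets had an unadjusted p under 0.05, 2020 of them higher in DBCP rats, where 1461 would be expected by chance. A plain 2-sample t statistic gave 0 passing and 3270 at an unadjusted p under 0.05. In replicate numbers 1 to 10 alone limma gave 0 passing and 897 at an unadjusted p under 0.05, and in numbers 11 to 20 alone 0 and 3912. The count moved with the setting. With the levels of the epididymal principal cell and leukocyte lists as covariates 1816 passed (1201 higher), among the brightest probe sets alone 132 (130 higher), and with 1 probe set per gene 1 (Asns, limma adjusted p = 0.0462). Without 6 arrays of low weight 0 passed, 1322 had an unadjusted p under 0.05 and 0 list levels passed. Of these 6, the DBCP arrays at the end of exposure were replicates 2, 13 and 20, with sperm tail levels of 8.59, 8.94 and 8.18 against a DBCP mean of 8.03. Without the 6 arrays the level of the sperm tail list differed by 0.08 instead of 0.18 and that of the spermatid regulators by 0.13 instead of 0.26, while the leukocyte level differed by -0.14 as before.

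After recovery, the comparison of 19 DBCP with 19 corn oil arrays asked whether any difference remained. Late spermatid transcripts lay close to 0, and the transcripts of red cells were lower in the DBCP rats. Hbb-b1 and Hbb, which encode the beta chain of hemoglobin, had log2 differences of -0.50 ± 0.14 and -0.47 ± 0.14, and Alas2, which starts heme synthesis in red cell precursors, -0.48 ± 0.13. Each lay below the corn oil mean on 17 of 19 DBCP arrays. Over all probe sets 0 passed limma's test. Adjusted over the list alone, these 3 of 11 erythrocyte genes fell (limma adjusted p = 0.0037 for Hbb-b1 and Alas2, 0.00495 for Hbb). The erythrocyte list level fell by 0.15 ± 0.04 (adjusted p = 0.00813, two-sided permutation test), on 17 of 19 arrays.

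The other genes of smallest p were Ms4a10 (0.15 ± 0.04), Lrp12 (0.16 ± 0.05; its 2 probe sets gave 0.04 and 0.16) and Rhoj, a small GTPase of endothelium (-0.18 ± 0.05), with a limma adjusted p of 0.983 each. Sperm genes had small differences, none passing: Prm1 -0.05 ± 0.07, Prm2 -0.04 ± 0.17, Tnp1 0.11 ± 0.22, Tnp2 -0.15 ± 0.14, Akap4 -0.02 ± 0.19, Odf1 0.01 ± 0.03, Ldhc -0.07 ± 0.15 and Smcp 0.00 ± 0.03. Odf1 and Smcp again lay near the top of the scale. Clu (0.03 ± 0.08), Cdkn1a (0.01 ± 0.05), Mgmt (0.01 ± 0.05), Gstm1 (-0.10 ± 0.11) and Hmox1 (-0.01 ± 0.07) did not pass either. Camera placed 5 lists lower. The leukocyte list had a median of -0.14 (23 of 29 below 0; Cd74 -0.19 ± 0.10; camera adjusted p = 8.53e-09, and adjusted p = 0.284 with an estimated correlation). The ribosomal proteins had -0.06 (54 of 64; camera adjusted p = 7.3e-08, and adjusted p = 0.490 with an estimated correlation). The immediate early genes had -0.06 (21 of 24; the phosphatase gene Dusp1 -0.35 ± 0.16 and the transcription factor gene Egr1 -0.28 ± 0.14; camera adjusted p = 1.42e-06, and adjusted p = 0.309 with an estimated correlation). The erythrocyte list had -0.06 (camera adjusted p = 7.51e-05, and adjusted p = 0.0936 with an estimated correlation). The glutathione list had -0.05 (33 of 38; camera adjusted p = 7.28e-04, and adjusted p = 0.516 with an estimated correlation). The 7 sperm lists had medians between -0.05 and 0.03 and 0 members passing. The medians of the chromatin, tail and Leydig lists were above 0 and their means below, and the ion channel list, which camera did not call, had a camera direction below the other genes although its median and mean were above 0.

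With limma 1084 probe sets had an unadjusted p under 0.05, where 1461 would be expected by chance. The plain 2-sample t statistic gave 0 passing and 1010 at an unadjusted p under 0.05. Without DBCP recovery replicate 7 alone 0 passed limma's test and 2135 had an unadjusted p under 0.05. With fry 0 lists passed. Without the 6 arrays of low weight the count at an unadjusted p under 0.05 was 2653, and the erythrocyte level kept its call (permutation test adjusted p = 0.00487). In replicate numbers 1 to 10 alone the erythrocyte level did not pass (-0.09, permutation test adjusted p = 0.440), and in numbers 11 to 20 it did (-0.22, adjusted p = 0.035).

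The interaction of DBCP and recovery tested whether the DBCP difference itself changed between the time points, which is also the test of whether the time effect differed between treatments. Late spermatid, ribosomal and respiratory chain transcripts had negative values, that is, their DBCP differences were lower after recovery than at the end of exposure. The spermatid regulators had a median of -0.30 (21 of 23 below 0; Spata18 -0.41 ± 0.16) and the energy metabolism list -0.23 (17 of 17; Gapdhs -0.56 ± 0.21). The ribosomal proteins had -0.18 (55 of 64; Rps29 -0.29 ± 0.14) and the respiratory chain -0.18 (40 of 47; Cox8a -0.21 ± 0.13). No gene passed. Of the 5 of smallest p, Rab18, a small GTPase of lipid droplets, had 0.37 ± 0.08 (its 2 probe sets gave 0.01 and 0.37). The others were Fndc8 (-0.69 ± 0.18), Vegfc, a growth factor of lymphatic vessels (0.32 ± 0.08), Mief1, a mitochondrial fission factor (-0.25 ± 0.07), and Mettl7b (0.27 ± 0.07), with a limma adjusted p of 0.454 each. Camera placed 11 lists lower. All 11 were lost with an estimated correlation (adjusted p between 0.350 and 0.659), and fry gave 0 (lowest adjusted p = 0.174). By the level per array, 0 of 23 list levels passed the two-sided permutation test (lowest adjusted p = 0.0924, the glutathione list). The medians and means of the epididymal principal cell, basal and clear cell and erythrocyte lists had opposite signs, as had the median and the camera direction of DNA repair. With limma 3170 probe sets had an unadjusted p under 0.05, and 5712 without DBCP recovery replicate 7. In replicate numbers 1 to 10 alone 763 did, and in numbers 11 to 20 alone 4403.

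Across all probe sets, the DBCP differences at the end of exposure and after recovery correlated negatively (Pearson r = -0.254, Spearman rho = -0.306). Probe sets are not independent replicates, and the comparisons share no array. The tail, leukocyte and erythrocyte levels of each array are plotted by group.

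**Figure D1:**
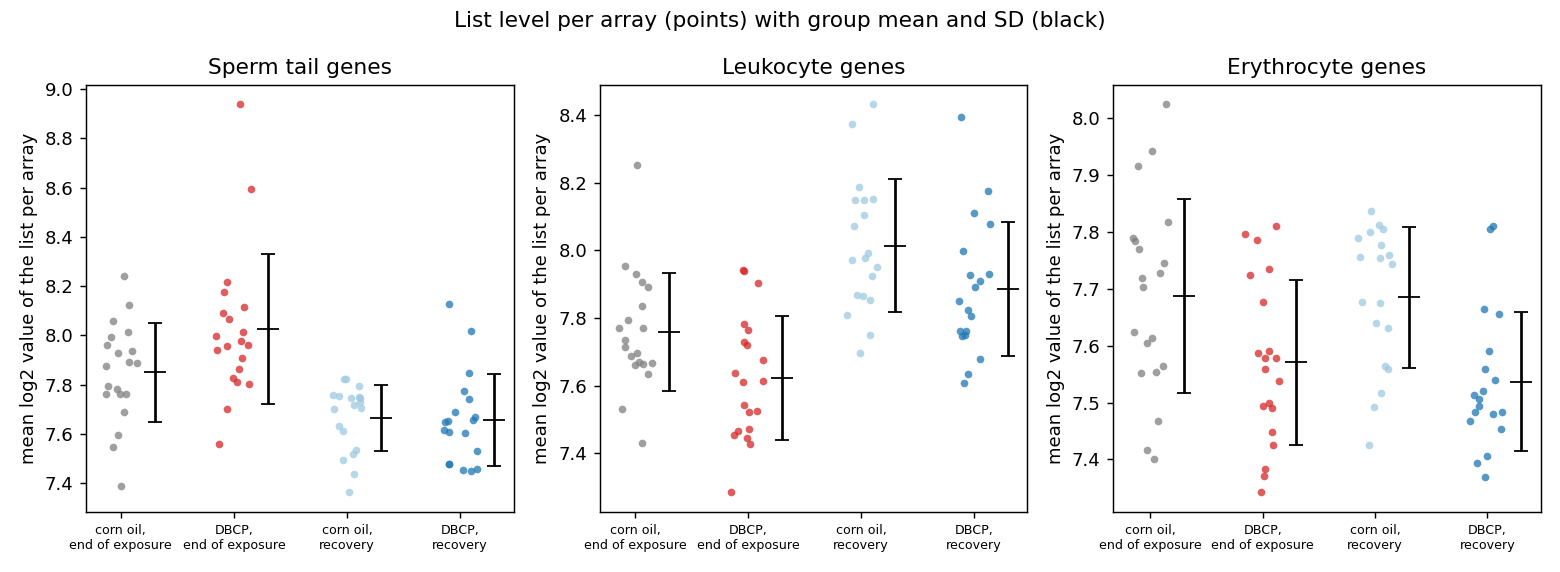
Mean log2 level of the sperm tail, leukocyte and erythrocyte lists on each of the 78 arrays (points, 19 or 20 per group) with the group mean and SD (black). The sperm tail mean was 7.85 in corn oil rats, 8.03 in DBCP rats and 7.66 in both recovery groups, and the leukocyte mean was 7.76, 7.62, 8.01 and 7.89 in corn oil, DBCP, corn oil recovery and DBCP recovery rats.

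In corn oil rats, the comparison of 19 recovery with 20 end of exposure arrays describes how the sperm samples differ between the collection times without the toxicant. Immune, ribosomal, respiratory chain and glutathione transcripts rose after recovery, and transcripts of late spermatids fell. The largest rise was that of Defb43, a beta-defensin (1.25 ± 0.18 or 2.37-fold, limma adjusted p = 6.84e-07, higher on 19 of 19 recovery arrays than the earlier mean). It was followed by Sarnp, an RNA export factor (1.00 ± 0.15), Cd59b, which blocks complement lysis (0.96 ± 0.13), and the adaptor Stap1 (0.96 ± 0.17). Elovl6, which elongates fatty acids (0.94 ± 0.16), and Acsl4, which activates arachidonic acid (0.94 ± 0.16), rose alike. The others were the translation inhibitor Pdcd4 (0.92 ± 0.13), the galactosyltransferase B3galt2 (0.91 ± 0.17), Ost4, of the enzyme that glycosylates new proteins (0.91 ± 0.15), and Fcer1g, the gamma chain of Fc receptors (0.91 ± 0.12).

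The largest fall was that of Spata19, a mitochondrial protein of spermatids, which fell by 1.08 ± 0.25 (limma adjusted p = 0.00117, below the earlier mean on 19 of 19 recovery arrays), and Tnp1 fell by 0.87 ± 0.22. The 8 others were Ms4a14 (-0.83 ± 0.23), the nucleotidase Nt5c1b (-0.79 ± 0.15), Spata31f3 (-0.78 ± 0.21), the sperm surface protein Spa17 (-0.77 ± 0.17), Garin1a (-0.74 ± 0.15), Ubqlnl (-0.74 ± 0.16), Fam229b (-0.73 ± 0.18) and Spata32 (-0.73 ± 0.17). Of the 23 spermatid regulators, 10 fell and 0 rose (11 fell when adjusted over the list alone). Among them were Spem1, needed to shed spermatid cytoplasm (-0.64 ± 0.15), and Spata20 (-0.58 ± 0.15). Of the 25 tail genes, 8 fell (10 adjusted over the list alone; Akap4 -0.72 ± 0.19, Gapdhs -0.56 ± 0.15). Of the 25 acrosome genes, 6 fell (6 adjusted over the list alone; Ace, whose testis form sits on sperm, -0.44 ± 0.10, the protease Prss21 -0.14 ± 0.03, Adam5 -0.50 ± 0.15). Of the 17 energy genes, 4 fell (4 adjusted over the list alone; Acsbg2, a fatty acid activating enzyme, -0.58 ± 0.15). No member of these 4 lists rose. Camera placed them lower (adjusted p = 0.00112, 0.00598, 0.0299 and 0.0193), and each call was lost with an estimated correlation (adjusted p = 0.498).

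Chromatin condensation had 6 falls and 1 rise, with 10 of 17 not passing (H1f7, a linker histone of spermatids, -0.38 ± 0.11, and the kinase gene Tssk6 -0.52 ± 0.16). The ion channels had 3 falls and 2 rises (the sperm sodium pump Atp1a4 -0.63 ± 0.16, the kinase Prkaca 0.16 ± 0.05). In the meiosis list 4 fell (Mael, which guards against transposons, -0.58 ± 0.17, Rec8, a meiotic cohesin, -0.22 ± 0.05). Camera called none of these 3 lists.

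Of the 29 leukocyte genes, 13 rose and 2 fell (14 and 3 adjusted over the list alone), with Cd74 at 0.77 ± 0.10 and the class II gene RT1-Ba at 0.61 ± 0.09. Among 38 glutathione genes 17 rose and 0 fell (19 and 3 adjusted over the list alone), such as catalase (Cat, 0.40 ± 0.07), Gstm1 (0.53 ± 0.11) and Gsta1 (0.66 ± 0.14). Of 64 ribosomal protein genes 31 rose and 1 fell (34 and 2 adjusted over the list alone; Rpl7 0.55 ± 0.08, Rpl28 0.63 ± 0.10). Of 47 respiratory chain genes 21 rose and 0 fell (23 and 0 adjusted over the list alone; Uqcrh of complex III 0.70 ± 0.11, Cox8a of cytochrome oxidase 0.48 ± 0.09). The chaperone genes Hspa8 (0.39 ± 0.06), Hsp90ab1 (0.44 ± 0.07) and Hsp90b1 (0.74 ± 0.13) were among 7 of 20 heat shock genes that rose, with 0 falling (7 and 1 adjusted over the list alone). Camera placed the 5 lists higher (adjusted p = 1.11e-05, 1.57e-04, 1.11e-09, 1.87e-06 and 0.0143), and each call was lost with an estimated correlation (adjusted p = 0.498).

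Of the other cell types, the epididymal basal and clear cell list had 4 rises and 2 falls among 12 genes (the proton pump subunits Atp6v0d2 0.87 ± 0.16 and Atp6v1b1 0.41 ± 0.10, Foxi1 0.65 ± 0.14). Principal cell genes went both ways, with 5 rises and 4 falls among 28 (the sperm surface glycoprotein gene Cd52 0.72 ± 0.13, the defensins Defb1 0.35 ± 0.07 and Defb22 -0.37 ± 0.07). Stroma had 2 rises and 3 falls among 20 (Dcn 0.73 ± 0.15, Vim 0.47 ± 0.12, the collagen gene Col4a1 -0.22 ± 0.05). Erythrocytes had 0 and 1 among 11 (Epb42 -0.22 ± 0.06), Sertoli cells 1 and 2 among 18 (Tjp1 0.32 ± 0.07) and Leydig cells 2 and 2 among 12 (Ptgds 0.71 ± 0.15, the steroidogenic enzyme gene Cyp11a1 -0.18 ± 0.05). The p53 list had 5 rises and 3 falls among 24 (Ccng1 0.51 ± 0.10), and DNA repair 3 and 1 among 26 (Rad23b 0.45 ± 0.10). Apoptosis had 4 and 3 among 22 (the survival gene Bcl2 0.56 ± 0.12), the immediate early genes 2 and 1 among 24 (Klf6 0.15 ± 0.04) and the cell cycle 1 and 4 among 23 (Ccnd2 0.41 ± 0.07, Ccnb2 -0.17 ± 0.05). Camera called none of these 11 lists. The stroma and Leydig lists had negative medians (-0.06 and -0.07) beside means of 0.01 and 0.00. The p53 list had a median of -0.03 beside a mean of 0.04, and DNA repair a median of -0.01 beside a mean of 0.01.

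By the level per array, 13 of 23 lists passed the two-sided permutation test. The levels of the ribosomal (0.21 ± 0.04, higher on 19 of 19 arrays), respiratory chain (0.21 ± 0.05), leukocyte (0.25 ± 0.06), glutathione (0.20 ± 0.05), heat shock (0.16 ± 0.04), basal and clear cell (0.15 ± 0.03), apoptosis (0.07 ± 0.02) and p53 lists (0.04 ± 0.01) rose. Those of the spermatid regulators (-0.26 ± 0.08), tail (-0.18 ± 0.05, lower on 19 of 19 arrays), acrosome (-0.12 ± 0.04), meiosis (-0.07 ± 0.02) and cell cycle lists (-0.04 ± 0.01) fell, with adjusted p between 0.00115 and 0.0277. With quantile normalization 11 lists passed, 8 higher and 3 lower after recovery. The list levels were not corrected for the median difference of all genes, which was -0.02 here, beside -0.04 for the cell cycle list. The differences of all lists are plotted for the 4 comparisons. The fry test called 15 lists.

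**Figure D2:**
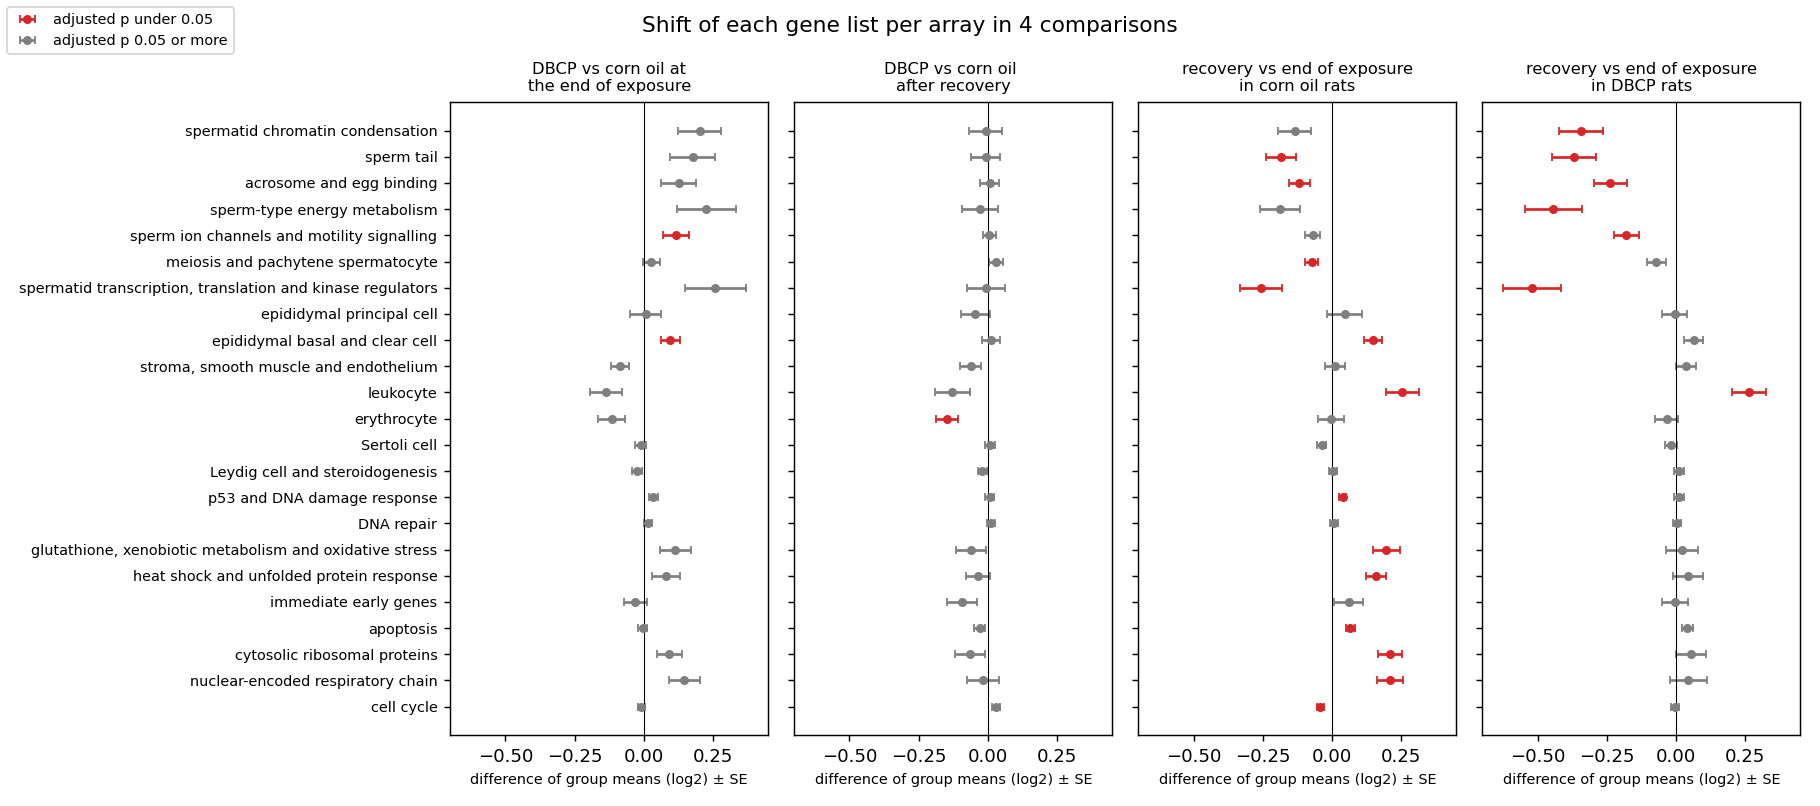
Difference of group means of each list's level per array (log2, points) with its standard error (bars) for the 23 gene lists in 4 comparisons of 19 or 20 arrays per group; red marks an adjusted p under 0.05 in the two-sided permutation test. The numbers of red lists were 2, 1, 13 and 7 from left to right, and the leukocyte list rose by 0.25 in corn oil rats and by 0.26 in DBCP rats between the end of exposure and recovery.

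In all, 7108 probe sets passed limma's test in corn oil rats, 3370 higher and 3738 lower after recovery, and 6 changed more than 2-fold. The split moved with the scaling, to 3850 higher and 2218 lower when each array was centred on its median, and with the epididymal principal cell and leukocyte levels as covariates 1220 passed, without Tnp1, Ms4a14 and Spata31f3. The labels give no date or batch, so a processing batch that followed the time point and the time itself cannot be told apart.

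In DBCP rats, the same comparison of 19 recovery with 20 end of exposure arrays showed a fall of spermatid transcripts and a rise of immune transcripts. The largest changes were falls. Spata19 fell by 1.63 ± 0.25 (to 0.322 of its earlier level, limma adjusted p = 1.68e-06), Akap4 fell by 1.37 ± 0.19 and Tnp1 fell by 1.29 ± 0.22, each on 19 of 19 arrays. The other 7 of the 10 largest falls were Spata31f3 (-1.39 ± 0.21), Nt5c1b (-1.36 ± 0.15), Ms4a14 (-1.33 ± 0.23), Phkg2, the phosphorylase kinase subunit of testis and liver (-1.32 ± 0.15), Spata32 (-1.31 ± 0.17), Ubqlnl (-1.28 ± 0.16) and Cby2 (-1.25 ± 0.19). The largest rises were those of Clec7a, a receptor for fungal glucans on myeloid cells (0.87 ± 0.11, limma adjusted p = 2.81e-08, on 18 of 19 arrays), Cd74 (0.79 ± 0.10) and Defb43 (0.73 ± 0.18). They were followed by the natural killer cell receptors Klrk1 (0.71 ± 0.11) and Klrd1 (0.64 ± 0.08), B3galt2 (0.69 ± 0.17), the lysophosphatidic acid receptor Lpar6 (0.66 ± 0.09), Cd59b (0.65 ± 0.13), Fcer1g (0.65 ± 0.12) and Ccr2, the chemokine receptor of monocytes (0.64 ± 0.09).

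Among the spermatid regulators 16 of 23 fell (18 adjusted over the list alone; Spata20 -1.08 ± 0.15, Spem1 -1.08 ± 0.15, Spata18 -0.79 ± 0.12). In the tail list 13 of 25 fell (16 adjusted over the list alone; Gapdhs -1.11 ± 0.15 and Fscb, a calcium-binding protein of the fibrous sheath, -1.01 ± 0.14). In the energy list 9 of 17 fell (12 adjusted over the list alone; Acsbg2 -0.97 ± 0.15). Chromatin condensation had 8 falls among 17 (10 adjusted over the list alone; Prm2 -1.09 ± 0.17, H1f7 -0.77 ± 0.11). The acrosome list had 9 among 25 (12 adjusted over the list alone; Adam5 -0.93 ± 0.15, Crisp2 -0.88 ± 0.15, Ace -0.78 ± 0.10), and the ion channels had 3 among 14 (5 adjusted over the list alone; Atp1a4 -1.07 ± 0.16, the bicarbonate-sensing cyclase Adcy10 -0.35 ± 0.08). No member of these 6 lists rose. Of the 29 leukocyte genes 14 rose and 1 fell (19 and 2 adjusted over the list alone; RT1-Ba 0.62 ± 0.09). Camera called these 7 lists (adjusted p between 1.45e-15 and 8.27e-04) and no other. With an estimated correlation the adjusted p was 0.0943 for 5 of them, 0.134 for the acrosome list and 0.142 for the leukocyte list. Their levels per array passed the two-sided permutation test as well, with adjusted p between 0.00115 and 0.00163. The differences were -0.52 ± 0.11 (regulators), -0.44 ± 0.10 (energy), -0.37 ± 0.08 (tail), -0.34 ± 0.08 (chromatin), -0.24 ± 0.06 (acrosome), -0.18 ± 0.05 (ion channels) and 0.26 ± 0.06 (leukocyte).

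Camera called none of the other lists. Meiosis had 6 falls and 1 rise among 23 (Mael -0.83 ± 0.17). The ribosomal proteins had 3 rises and 2 falls among 64 (Rps4x 0.46 ± 0.12, Rps20 -0.29 ± 0.06), and the respiratory chain 3 and 1 among 47 (Uqcrh 0.42 ± 0.11). The heat shock list had 6 and 3 among 20 (Hspa8 0.35 ± 0.06; Herpud1, of protein degradation at the endoplasmic reticulum, -0.75 ± 0.14) and the glutathione list 2 and 2 among 38 (Cat 0.27 ± 0.07; Gstm5 -0.70 ± 0.12; Gpx4, the selenoprotein of the sperm midpiece, -0.52 ± 0.13). In the principal cell list Cst8, a cystatin of testis and epididymis, fell by 0.91 ± 0.15, and in the Leydig list Lhcgr, the receptor for luteinizing hormone, fell by 0.55 ± 0.10. Stroma had 3 rises (Lum 0.32 ± 0.08), basal and clear cells 1 fall (Car2 -0.33 ± 0.08) and Sertoli cells 1 fall (Inha -0.20 ± 0.05), while 0 erythrocyte genes passed (Hbb 0.06 ± 0.14). Of the p53 list 2 rose and 3 fell (Rrm2b 0.25 ± 0.05, Cdkn1a -0.21 ± 0.05), and of DNA repair 2 and 3 (Nbn 0.21 ± 0.04, Lig3 -0.36 ± 0.07). Of apoptosis 1 and 2 (Bcl2 0.39 ± 0.12, Bcl2l1 -0.16 ± 0.04) passed, and of the cell cycle 2 and 1 (Plk1 -0.33 ± 0.07). With limma 0 immediate early genes passed. The stroma, Leydig, p53, epididymal principal cell and cell cycle lists had medians, means or camera directions of opposite sign.

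In DBCP rats 3933 probe sets passed limma's test, 2126 higher and 1807 lower after recovery, and 73 changed more than 2-fold. The split turned among the brighter probe sets (1011 higher and 1364 lower), the brightest (530 and 818) and in replicate numbers 11 to 20 (120 and 385). Between the treatments 1199 probe sets were higher after recovery in both (245 expected for independent lists) and 851 lower in both (231 expected). In opposite directions 0 passed (208 and 272 expected). The comparisons share no array, but they share the estimate of the spread of each probe set and any batch that followed the time point. The counts expected for independent lists are therefore a low reference. The falls of Akap4, Spata19 and the other spermatid genes had larger values in DBCP rats than in corn oil rats, but 0 probe sets passed the interaction test of that difference (limma, 3170 at an unadjusted p under 0.05). By replicate number, 3035 probe sets passed in numbers 1 to 10 and 505 in numbers 11 to 20, against 4768 and 385 in corn oil rats. With limma 0 passed the test of whether the time effect differed between these sets of numbers in either treatment (lowest limma adjusted p = 0.331 in corn oil and 0.638 in DBCP rats; 2518 and 2006 at an unadjusted p under 0.05).

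**Figure D3:**
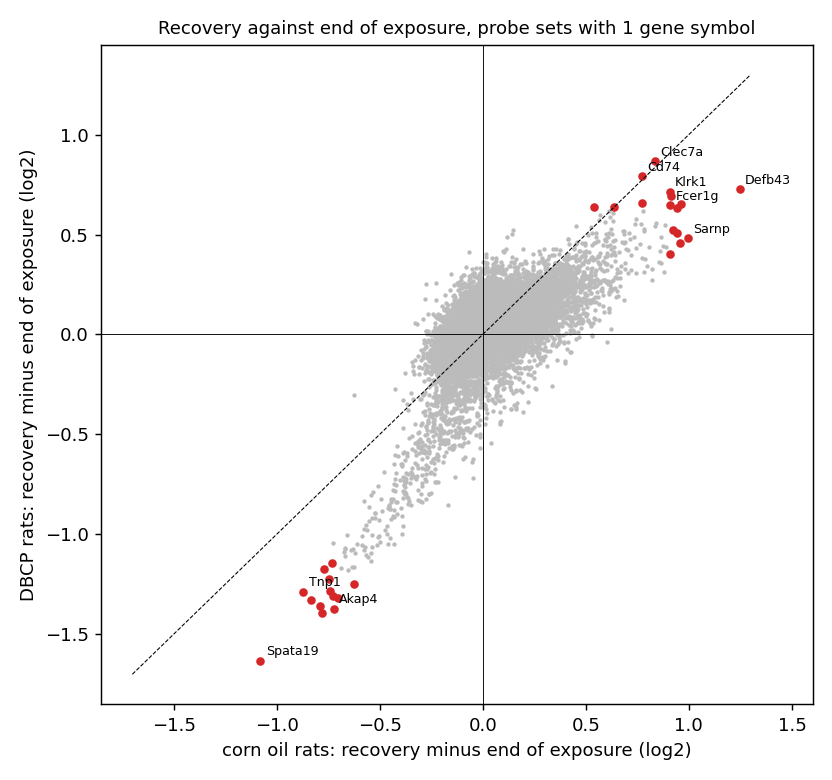
Log2 difference between recovery and end of exposure for each of the 15310 probe sets with 1 gene symbol, in corn oil rats (x axis) and in DBCP rats (y axis); red points are the named genes and the dashed line marks equal values. Spata19 lies at -1.08 and -1.63, Defb43 at 1.25 and 0.73 and Cd74 at 0.77 and 0.79.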

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

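The tests of explanations and the other splits of the arrays in this part were chosen only after the results were seen; the interaction test was not.

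Camera's test of the interaction, with its preset correlation, placed 11 gene lists below the other genes. Relative to those genes, their DBCP difference was lower after recovery than at the end of exposure. By the level per array, 0 of 23 lists passed the two-sided permutation test of the interaction (lowest adjusted p = 0.0924). The median log2 values were -0.30 for the spermatid regulators, -0.23 for energy metabolism, -0.21 for chromatin condensation, -0.12 for the sperm tail, -0.092 for the acrosome and -0.053 for the ion channels. They were -0.18 for the ribosomal proteins, -0.18 for the respiratory chain, -0.15 for the glutathione list, -0.13 for heat shock and -0.045 for the immediate early genes. With an estimated correlation all 11 calls were lost (lowest camera adjusted p = 0.350). Of 100 splits of the arrays, the real one included here and in every count of splits, 6 gave as many lists as the real one (11, highest other 14), so chance cannot be excluded. For single probe sets limma gave 0 passing in the interaction (3170 at an unadjusted p under 0.05). A count of 0 is reached by every split (100 of 100), so the splits say nothing about it. The highest other split called 3297, and the cause was not tested.

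The 3386 probe sets with an unadjusted p under 0.05 in DBCP against corn oil rats at the end of exposure exceeded the 1461 that chance would give, and 4 of 100 splits gave as many (highest other 5216). In replicate numbers 1 to 10 alone the count was 897, and in numbers 11 to 20 alone it was 3912. Between these sets within the DBCP arrays at the end of exposure, 0 passed and 4194 had an unadjusted p under 0.05. With limma 0 passed the test of whether the DBCP difference itself differed between the sets (1216 at an unadjusted p under 0.05). What set numbers 11 to 20 apart was not tested. Fewer carried-over leukocytes and epididymal cells on the DBCP arrays were tested with the levels of both lists as covariates. The count was then 8458, not lower, and other splits with these covariates reached up to 6892. This does not decide the question, since the leukocyte level was itself lower on the DBCP arrays (-0.14 ± 0.06). The principal cell level showed no fall (0.01 ± 0.06). A few unusual arrays may carry the excess. Without the 6 arrays of low weight, 3 of them DBCP arrays at the end of exposure (replicates 2, 13 and 20), the count was 1322. Of 100 splits 45 gave as many (median of the others 1258). An effect of DBCP on sperm stays open as well. With both covariates 1816 probe sets passed, and only the real split gave as many (1 of 100, highest other 32). The other splits break the link of the leukocyte level with treatment, so they cannot show that these calls come from sperm. Without the 6 arrays and with both covariates 39 passed, and 2 of 100 splits gave as many (highest other 94). At an unadjusted p under 0.05 this last setting gave 3368, and 5 of 100 splits gave as many. Chance cannot be excluded for that count, so it does not decide whether the low-weight arrays carry the whole excess.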

How the results depend on the processing

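Annotated probe sets alone, fits without arrays of low weight, leukocyte and erythrocyte covariates, each set of replicate numbers alone and the combined settings were chosen only after the results were seen. The other settings were not. The cause was not tested for the changes given here, unless fewer probe sets or arrays, or a list used as its own covariate, account for it. In DBCP against corn oil rats at the end of exposure, limma's 0 passing (3386 at an unadjusted p under 0.05) became 1816 with epididymal principal cell and leukocyte covariates, 421 with leukocyte and erythrocyte covariates, 132 among the brightest probe sets, 39 without low-weight arrays and with the first covariates, and 1 with 1 probe set per gene. Leaving out each array gave 0 to 14: 14 without DBCP replicate 12, 10 without corn oil replicate 4, 2 without DBCP replicate 4, and 1 without DBCP replicate 7 or 16 or corn oil replicate 5 or 9. After recovery against end of exposure in corn oil rats, 7108 became 3166 (brightest), 4382 (1 probe set per gene), 4679 (annotated), 1220 and 619 (the same pairs of covariates) and 385 (numbers 11 to 20); in DBCP rats 3933 became 2375 (brighter probe sets), 1348 (brightest) and 505 (numbers 11 to 20). Leaving out each array gave 5802 to 7849 in corn oil and 3303 to 4558 in DBCP rats. With the replicate block the counts were 0 in each DBCP contrast and the interaction, 6226 in corn oil and 3887 in DBCP rats over time. Of the gene lists, camera with an estimated correlation called 0 in each of the 5 contrasts; without low-weight arrays it called 0, 0, 0, 0 and 4, the last in DBCP rats over time. With fry, 2 passed at the end of exposure, 0 after recovery, 0 in the interaction and 15 in corn oil rats over time. After recovery, 8 passed without low-weight arrays and 3 with leukocyte and erythrocyte covariates. Those covariates reversed list medians: immediate early genes to 0.054 at the end of exposure and -0.075 in corn oil rats over time, leukocytes to -0.032 in corn oil and -0.014 in DBCP rats (by construction), and in DBCP rats glutathione to -0.11, ribosomal proteins to -0.090 and the respiratory chain to -0.11. Of the list levels in the permutation test at the end of exposure, the 2 higher lists (ion channels, basal and clear cells) lost their calls with quantile normalization and 2 lower ones (leukocytes, stroma) gained them; 0 passed without low-weight arrays, 0 in numbers 1 to 10 and 1 in numbers 11 to 20. After recovery 0 passed in numbers 1 to 10, where the erythrocyte list lost its call. In corn oil rats over time 2 passed in numbers 11 to 20, and in DBCP rats 3 in either set. The 3' minus 5' covariate and the RNA integrity proxy were not run, as no control probe sets were found. Of 40 calls of named genes 37 held with the epididymal principal cell and leukocyte covariates (9 of 41 others gained a call), 32 with the leukocyte and erythrocyte covariates (5 gained) and 20 in numbers 11 to 20 (0 gained). Among the brightest probe sets 37 of 37 held and 5 of 28 others gained a call. The number of arrays limits precision: the median SE was 0.06.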

Other observations

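The lists of immune cell types, the tests of explanations and the other splits of the arrays in this part were all chosen only after the results were seen.

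Among immune cell types, genes of natural killer and cytotoxic T cells and of macrophages and dendritic cells rose after recovery. In corn oil rats 18 of 26 rose and 1 fell (Klrb1c 0.69, Cd7 0.84, Klrc3 0.78), and the list level rose by 0.38 ± 0.04 on 19 of 19 arrays (camera adjusted p = 0.00528 with an estimated correlation). In DBCP rats 18 rose and 0 fell (Klrd1 0.64, Klrk1 0.71, Klrc3 0.62), and the level rose by 0.30 ± 0.04 on 19 of 19 arrays (camera adjusted p = 0.0121 with an estimated correlation). Of 21 macrophage and dendritic cell genes, 12 rose and 1 fell in corn oil rats (Clec7a 0.84) and 13 rose and 0 fell in DBCP rats (Clec7a 0.87, Ccr2 0.64). Neutrophil genes went both ways, with 2 rises and 4 falls among 17 in corn oil rats (Ltf 0.63, Lcn2 -0.28) and 4 and 2 in DBCP rats (Ltf 0.50, Lcn2 -0.46). Of 8 B cell genes 2 rose and 2 fell in corn oil rats, and 0 passed limma's test in DBCP rats. Of 20 interferon-induced genes 5 rose in corn oil rats (Gbp5 0.56) and 3 in DBCP rats (Gbp5 0.47, Gbp2 0.30). Of 30 proteasome genes 8 rose and 1 fell in corn oil rats, and 2 rose and 2 fell in DBCP rats. Of the natural killer list 3 genes and of the macrophage list 9 are also in the leukocyte list. Camera p-values of the added lists were adjusted over these lists alone, and lists chosen from the same data give no independent support. The fixed leukocyte list lost its camera calls over time with an estimated correlation. In DBCP against corn oil rats at the end of exposure the macrophage and dendritic cell level fell by 0.12 ± 0.04 (two-sided permutation test adjusted p = 0.0313 over 30 tests), on 16 of 20 arrays. Its camera adjusted p was 1.88e-05, and 0.240 with an estimated correlation.

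The higher leukocyte transcripts after recovery may come from more leukocytes carried over with the sperm, or from a change within those cells. Cd74 had mean levels of 11.1, 10.9, 11.9 and 11.7 and Lyz2 of 10.2, 9.88, 10.6 and 10.3 in corn oil, DBCP, corn oil recovery and DBCP recovery rats. No step in the labels' protocols was aimed at leukocytes, although the ammonium chloride buffer lyses red cells. The leukocyte list rose more than the erythrocyte list, by 0.26 in corn oil rats (two-sided permutation p = 1e-05, the smallest it can give) and by 0.30 in DBCP rats (p = 4e-05). It also rose more than the stroma list, by 0.24 and 0.23. This does not decide whether a lower share of sperm raised the other cell types. The protocols lysed red cells, and some erythrocyte genes were dim (mean levels of 5.17 for Ahsp and 5.96 for Rhag). In corn oil rats single genes of other cell types also rose (Dcn, Defb1, Atp6v0d2), while others fell (Col4a1, Defb22). A processing batch that followed the time point cannot be told apart from the recovery period, since 0 label fields give a date or batch, and age is open too.

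Less blood carried over with the sperm, as a candidate source of the lower erythrocyte genes in DBCP rats after recovery, cannot be told apart from other sources. The 3 erythrocyte genes with a mean level over 8 had a median log2 difference of -0.48, with mean levels of 11.9 (Hbb), 10.6 (Hbb-b1) and 8.36 (Alas2), but these are the genes that showed the fall, so their median decides nothing. Of the 11 list members 0 are in another list. The lysis step of the protocols is directed at red cells, but how much of them it left was not measured. Arrays of low weight are argued against as the cause, since without them the permutation test gave an adjusted p of 0.00487. An effect of DBCP on red cells was not tested.

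Of 100 splits of the arrays, the real one included, only the real one (1) gave as many passing probe sets in corn oil rats over time (7108, highest other 7). This makes chance unlikely there, but 1 of 100 is the smallest share that so few splits can give. In DBCP rats over time the real one and another (2) did (3933, highest other 5717). What set that other split apart was not tested. Without the 6 arrays of low weight only the real one (1) did (3409, highest other 35). With the epididymal principal cell and leukocyte covariates as well, only the real one (1) did (3938, highest other 1). In DBCP against corn oil rats the real count was 0 at the end of exposure (limma; 3386 at an unadjusted p under 0.05), there without the arrays of low weight (1322) and after recovery (1084). All 100 splits reach 0, so they say nothing about these counts. The highest others were 46, 471 and 8, and the cause of the 471 was not tested. With leukocyte and erythrocyte covariates at the end of exposure only the real one (1) reached its count (421, highest other 107). The other splits do not keep the link of these covariates with treatment, so this does not decide the source of the calls. Chance cannot be excluded for the number of lists that camera called: 5 splits gave as many at the end of exposure (13, highest other 14), 49 after recovery (5, highest other 12), 17 in corn oil rats over time (9, highest other 13) and 48 in DBCP rats over time (7, highest other 12). The shifts of these lists over time were tested apart from that number. By the level per array, 8 of the 9 lists in corn oil rats and 7 of the 7 in DBCP rats passed the two-sided permutation test of the group labels. The exception was energy metabolism in corn oil rats (-0.19 ± 0.07, adjusted p = 0.0659). Chance cannot be excluded either for the negative correlation of the DBCP differences, as 26 splits gave an r as far from 0 as -0.254 (highest other 0.583).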
